A study of Mus musculus with 10 samples.

How the data were processed

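The data were RNA levels measured on 1-colour Affymetrix mouse arrays in 10 samples of primary mouse cells. Per the labels, the cells were neutrophils (2 wild-type and 2 knockout samples), macrophages (2 wild-type and 2 knockout samples) and B cells (1 wild-type and 1 knockout sample). All mice were labelled C57BL/6, male and 3 months old. The labels state that cells were isolated from a mouse and cultured by standard protocols, that RNA was taken with Tri Reagent and then RNeasy Plus, and that it was labelled with biotin. The submitters' processing notes name GCOS as a tool, without its role or version. The background correction, the summary of probes into probe sets and the scaling between arrays were not given in the sources used here. The deposited values are log2 signals, 1 per probe set and array. The log2 unit was read from the values themselves, which run from 2.60 to 15.35 with no negative value.

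The labels do not name the deleted gene, so the deletion itself was not examined. They also do not say whether replicates came from separate animals or cultures, so every p-value of a gene here measures the spread between these samples only. Replicate numbers were not used to pair samples. The design text speaks of 6 samples and 10 are listed, and all 10 were used. Depth does not apply to arrays, and the number of arrays limits the precision.

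Of 45101 probe sets, 64 array controls were left out. Of the others, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none, and 34741 matched an Entrez gene of the mouse annotation (GRCm38.p6), which changed 0 symbols. A gene was represented by the probe set with exactly 1 symbol that had the highest mean over the 10 arrays, which gave 18193 genes. Arrays were used as deposited where the 2%-trimmed means of their linear values differed by up to 5%. This held within neutrophils (2.23%), macrophages (3.12%) and B cells (0.671%). For the comparisons across cell types (29.7% and 30.1%) each array was scaled to the mean trimmed mean. Genes with a mean below the 40th percentile over the compared arrays were left out, which left 10916 genes per comparison above log2 signals of 6.32 (neutrophils), 6.52 (macrophages) and 6.48 (both wild types).

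Groups were compared with limma (version 3.58.1, R 4.3.3) by lmFit and eBayes with a variance trend, two-sided, with the 2 compared groups in each fit. Each fit had 2 residual degrees of freedom, and the prior added 4.28 (neutrophils), 1.82 (macrophages) and 1.78 (both wild types). The SE and p of a gene therefore rest partly on the spread of genes of like level, and an SE can differ from what the gene's own SDs give. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The difference between the knockout effects of neutrophils and macrophages was an interaction contrast over 8 arrays and 10106 genes. B cells had 1 array per genotype and no test. There, the median of a gene list was placed among 10000 random lists matched on mean level (seed 20140).

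Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and fry (a rotation test of whether a list's genes move, on balance, in 1 direction) beside it. Lists with fewer than 3 tested genes were not tested. At the preset correlation camera compares list genes with the other genes, so its p-value is not a measure of spread between samples. At an estimated correlation camera rests on the few residual degrees of freedom of a fit. It gave no call even for secondary and tertiary granule genes between the wild types (10 of 10 higher, median 8.48, adjusted p = 0.563). A call that ended there is undecided by that version. Fry did call that granule list (adjusted p = 0.000375), but it called no list between genotypes. Its smallest adjusted p there was 0.167 in neutrophils and 0.670 in macrophages. The lists covered reported targets of miR-223, miR-155, miR-122 and let-7, markers of primary granules, secondary and tertiary granules, mature neutrophils, macrophages, B cells, plasmablasts, T cells, NK cells, erythroid cells, dendritic cells, and eosinophils, basophils and mast cells, and genes of inflammation, interferon response, cell cycle, MHC class II presentation, lysosome, cholesterol synthesis, glycolysis, early response and stress, class switching and germinal centre, microRNA machinery, mRNA deadenylation and decay, and the Y chromosome with Xist. The miR-223 and miR-155 lists came from general knowledge of microRNAs in these cell types, since the series title concerns microRNAs. Within a list, members were also counted by a p adjusted over the list alone. Some list genes were not analysed here.

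The comparisons, the lists, the settings and the rule for named genes were chosen before the data were examined. Named were the 10 genes higher and the 10 lower with the largest log2 fold change among the genes called with groups that did not overlap. Where a direction had fewer than 3, the 5 with the smallest p in that direction were also named. In B cells, the 10 highest and 10 lowest differences among genes at or above the 60th percentile of mean level were named. Members of a list were named as examples of it. Other genes are stated as chosen after their values were seen.

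Alternatives were no filter and a filter at the 60th percentile, quantile normalization, the mean of all probe sets of a gene, leaving out probe sets ending in _x_at, every probe set tested, no variance trend, replicate number as a block, a joint fit of 8 arrays, and leaving out each replicate. Array weights, list tests in macrophages without wild-type replicate 2 and list tests of the interaction were added after the data were seen. Seed matches were not run, since no 3′ UTR sequence was used here. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

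The tests were run on simulated data with known changes. With 2-fold and 4-fold changes in 100 genes each, the neutrophil fit found 97 and 100 of them with 7 false calls, and the macrophage fit found 0 and 0. With changes of up to 64-fold in 50 genes per size, the macrophage fit found 2 at 2-fold, 32 at 4-fold, 43 at 16-fold and 47 at 64-fold, with 6 false calls. Lists of 20 genes shifted by 0.5 were found in every fit, and 0 of 50 unshifted lists in neutrophils and 2 of 50 in macrophages had an unadjusted p under 0.05. The simulated genes were drawn independently, with equal spread in both groups. Real lists had estimated correlations of up to 0.781 in neutrophils (interferon response) and 0.999 in macrophages (cell cycle). The rate of false list calls therefore does not carry over to the real lists.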

Results

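Signals were measured in 10 samples: neutrophils, the granulocytes that respond first to infection (2 wild-type and 2 knockout), macrophages, which engulf debris and microbes (2 wild-type and 2 knockout), and B cells, which make antibodies (1 wild-type and 1 knockout). Median log2 signals over the 45037 probe sets of an array were 6.30 to 6.34 in neutrophils, 6.49 to 6.53 in macrophages, and 6.56 (wild type) and 6.57 (knockout) in the B cell arrays. The SD of the log2 difference between the 2 wild-type neutrophil arrays was 0.134, and between the 2 knockout arrays 0.168. Between genotypes it was 0.173 to 0.211 in neutrophils and 0.117 in B cells. In macrophages the 2 knockout arrays differed by an SD of 0.216, whereas the 2 wild-type arrays differed by 0.722, and 1080 genes (9.89%) differed between these by over 1. Wild-type macrophage replicate 2 lay 0.708 to 0.727 from the knockout arrays and wild-type replicate 1 lay 0.287 to 0.327 from them.

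**Figure D1:**
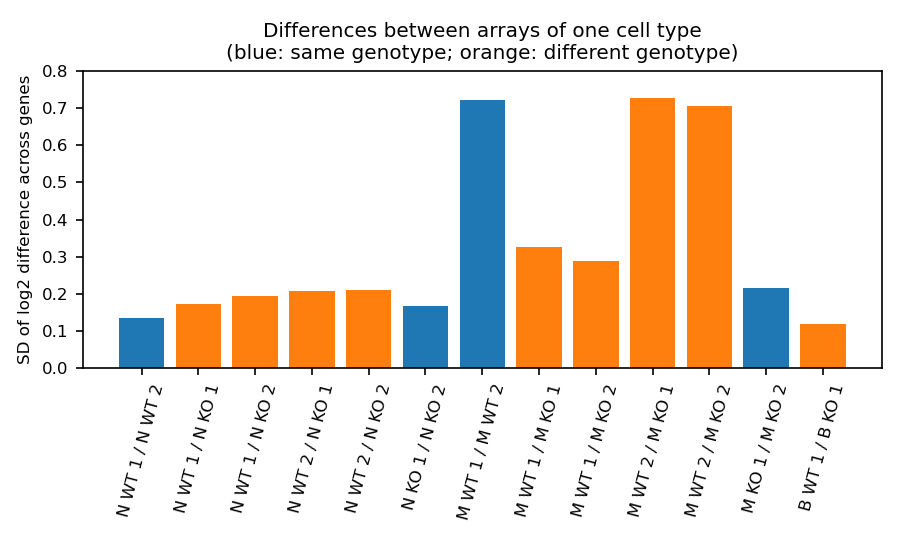
SD across genes of the log2 difference for each pair of arrays of a cell type, with N for neutrophils, M for macrophages and B for B cells, blue for pairs of the same genotype and orange for pairs of different genotype. The pairs with wild-type macrophage replicate 2 lie between 0.708 and 0.727, and the other macrophage pairs between 0.216 and 0.327.

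The comparison of knockout with wild-type neutrophils asked which genes differed with the genotype in these cells (n = 2 per group). Hebp1, a heme-binding protein, rose from a log2 signal of 8.18 ± 0.04 to 11.33 ± 0.57 (mean ± SD), which is 8.89-fold (log2 fold change 3.15, SE 0.24, adjusted p = 0.00906). Emp1, an epithelial membrane protein, rose from 6.74 to 9.03 (2.29, SE 0.13, adjusted p = 0.00482). Apoe, the lipid-carrying apolipoprotein E, fell from 10.99 to 8.59 (−2.40, SE 0.17, adjusted p = 0.00837), and Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, fell from 7.93 to 6.21 (−1.73, SE 0.16, adjusted p = 0.0190). As groups, early response genes, inflammatory mediators and interferon-response genes were lower, and genes of cholesterol synthesis and of the cell cycle were higher. Each was called by a list test at a preset correlation, and each call ended with an estimated correlation and by fry. In all, 19 genes were higher and 20 lower, with 680 and 689 at an unadjusted p under 0.05. The 2 groups did not overlap in 4706 genes (43.1%), where chance gives 33.3%. Genes do not vary independently, so such a share, here and below, is not a test of a difference between groups.

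Among the other genes that rose, Gdpd3, which cleaves lysophospholipids, went from 10.37 to 11.95 (1.58, adjusted p = 0.0154), Sash1, an adaptor protein, from 8.39 to 9.37, and BC018473 from 12.63 to 13.60 (0.97, SE 0.05, adjusted p = 0.00482). BC064078 rose by 1.09, Lsm12 by 1.03, Hal, the histidine ammonia-lyase, by 0.95, Gm6958 by 0.94, and Slc15a2, a peptide transporter, by 0.89, with adjusted p from 0.0181 (BC064078) to 0.0475 (Gm6958 and Slc15a2). Atp10d, a phospholipid flippase, fell from 10.14 and 9.85 to 8.52 and 8.53 in the arrays (log2 fold change −1.47, SE 0.10, adjusted p = 0.00837) and Bend4 fell from 9.69 to 8.41 (−1.28, SE 0.06, adjusted p = 0.00482). Cd300ld, an immune receptor, fell from 10.19 to 8.85, and Itgb3, the integrin β3 chain, fell with a log2 fold change of −1.33 (adjusted p = 0.02 for both). Gpc3, a cell-surface glypican, changed by −1.25, Tesc, a calcium-binding protein, by −1.23, Scrg1 by −1.13 and Dhx40, a helicase, by −0.95, with adjusted p from 0.00730 (Tesc) to 0.0466 (Gpc3). The calls depended on the variance model: 1 gene (Bend4, lower) was called without the variance trend and 0 in the limma joint fit of 8 arrays, which gave 116 higher and 139 lower at an unadjusted p under 0.05. Leaving out 1 array, which leaves 1 array in a group, changed the counts in both directions, as given with the processing below. The 60th percentile filter gave 11 higher and 13 lower.

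**Figure D2:**
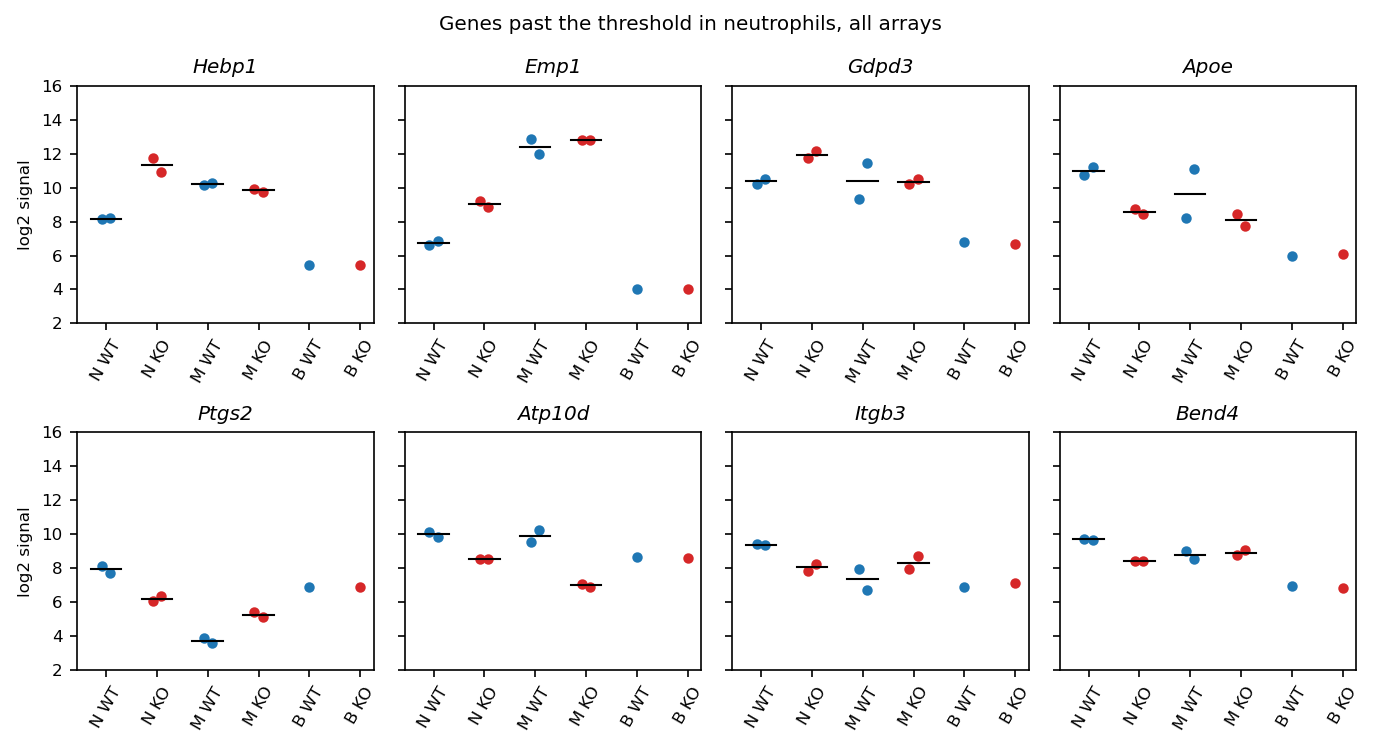
Log2 signal of 8 genes called in neutrophils, 1 point per array, in neutrophils (N), macrophages (M) and B cells (B), with wild type in blue, knockout in red and a black line at the mean of 2 arrays. Hebp1 lies at 8.15 and 8.21 in wild-type neutrophils and at 11.74 and 10.93 in knockout neutrophils.

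Early response genes, the transcription factors and feedback regulators that cells switch on within minutes of a stimulus, were lower in knockout neutrophils (median log2 change −0.28, 11 of 12 tested members negative, adjusted p = 3.95e-08). Over all genes 1 member, Ier3, fell, and 8 members fell when adjusted over the list alone. Egr1 went from 12.97 to 12.28, Dusp1 from 12.37 to 11.71, and Junb changed by −0.29. Inflammatory cytokines and mediators were lower in the same direction (median −0.29, 10 of 11 negative, adjusted p = 2.25e-07), with Cxcl2 and Ptgs2 called over all genes and 6 members adjusted over the list alone. Cxcl2, a neutrophil-attracting chemokine, fell from 12.19 to 11.77, and Il1b fell from 11.23 to 10.45. With an estimated correlation the adjusted p was 0.371 for each of these lists, and fry gave an adjusted p of 0.167 for each.

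Interferon-response genes were also lower (median −0.47, 12 of 13 negative, adjusted p = 1.76e-06, but adjusted p = 0.536 with an estimated correlation). None of these members passed over all genes, and Oasl1 (9.58 to 7.91), Irf7, a transcription factor of the response (10.43 to 9.58), and Usp18 (−0.69) fell when adjusted over the list alone. The list's mean deviation was 0.54 in wild-type replicate 2, −0.01 in wild-type replicate 1 and −0.26 and −0.28 in the knockout arrays. MHC class II presentation genes were lower (median −0.33, 7 of 8 negative, adjusted p = 0.0015, but adjusted p = 0.536 with an estimated correlation and 0.0752 without knockout replicate 2). H2-Aa (12.01 to 11.42), H2-Ab1, H2-Eb1 and Cd74 fell when adjusted over the list alone, and the list's mean deviation was 0.30 in wild-type replicate 2 and −0.24 in knockout replicate 2.

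All 11 tested genes of cholesterol synthesis were higher in knockout neutrophils (median 0.19, adjusted p = 3.95e-08, but adjusted p = 0.371 with an estimated correlation). When adjusted over the list alone 8 of them rose, among them Sc5d (11.62 to 11.95), Fdps (13.16 to 13.43) and Sqle (0.27), and 0 passed over all genes. Cell-cycle genes were higher by a median of 0.11 (18 of 19 positive, adjusted p = 7.27e-06) and glycolysis genes lower (median −0.12, 11 of 11 negative, adjusted p = 4.91e-06). Neither list had a member past the threshold, and both had an adjusted p of 0.536 with an estimated correlation. In the joint fit of 8 arrays the adjusted p was 0.417 for cholesterol synthesis and for MHC class II, 0.602 for the cell cycle and 0.204 for glycolysis.

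Markers of granulocyte stages moved apart by small amounts. Primary granule genes, made early in granulocyte development, were higher (median 0.11, 5 of 6 positive, adjusted p = 0.00159), and Elane, neutrophil elastase, rose from 14.61 to 14.73 when adjusted over the list alone. Mature neutrophil genes were lower (median −0.12, 8 of 9 negative, adjusted p = 0.00159), with Fpr2, a formyl peptide receptor (−0.31), Clec4d, Il1r2 and Csf3r past the threshold adjusted over the list alone. Both lists had an adjusted p of 0.536 with an estimated correlation, and in the joint fit of 8 arrays 0.166 (primary granule) and 0.0994 (mature neutrophil). Secondary and tertiary granule genes had a median of −0.04 (3 positive, 7 negative, adjusted p = 0.278).

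Markers of other cell types gave mixed values in neutrophils. Eosinophil, basophil and mast cell genes had a median of 0.29 (4 of 6 positive, adjusted p = 0.0176, but adjusted p = 0.536 with an estimated correlation). Mcpt8, a basophil protease, rose from 11.70 to 12.11 over all genes, Cpa3, Fcer1a and Ms4a2 rose when adjusted over the list alone, and Prg2, the eosinophil major basic protein, fell from 11.45 to 11.03 by the same measure. The adjusted p of this list was 0.122 without wild-type replicate 2 and 0.0501 without knockout replicate 1. T cell markers had a median of 0.01 and a mean of 0.25 (adjusted p = 0.484), with Thy1 (6.30 to 7.56) and Cd3d (7.14 to 7.59) higher when adjusted over the list alone. Macrophage (adjusted p = 0.788), B cell (0.837) and plasmablast (0.149) markers gave no call as lists, although C1qb rose by 0.27 and Cd14 and Sdc1 fell by 0.39 and 0.51 when adjusted over the list alone. Lysosome (0.837), class switching (0.788), microRNA machinery (0.839), mRNA decay (0.381) and Y-linked genes with Xist (0.374) gave no call either.

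The comparison of knockout with wild-type macrophages (n = 2 per group) asked the same question in these cells. Ifi202b, an interferon-inducible protein of the p200 family, rose from 4.73 to 11.44, which is 105-fold (log2 fold change 6.71, SE 0.13, adjusted p = 0.0141), and was the only gene called with these settings. It lay at 4.67 and 4.79 in the wild-type arrays and at 11.42 and 11.46 in the knockout arrays. Both wild-type signals were below the 25th percentile of their arrays (4.89 and 4.98), so the fold was read against signals not shown to be above background and is a lower bound. In wild-type neutrophils it lay at 9.91 and 8.83, and in the B cell arrays at 5.18 and 5.03. By limma 0 genes were lower, with 244 higher and 208 lower at an unadjusted p under 0.05 (700 and 1061 without wild-type replicate 2), and 40.4% of genes had groups that did not overlap, where chance gives 33.3%. The wild-type arrays differed between themselves by more than the knockout arrays did, as given above. Without wild-type replicate 2, 2 genes were called, Ifi202b (6.77, adjusted p = 0.00273) and Scd2 (lower). Without wild-type replicate 1 it was 2449 higher and 1943 lower, and without either knockout replicate 0. The 60th percentile filter gave 0 higher (131 at an unadjusted p under 0.05), and the joint fit of 8 arrays gave 14 higher and 7 lower.

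The genes with the next smallest p did not pass the threshold. Ifi44l, another interferon-induced gene, was at 4.41 in wild-type and 8.89 in knockout macrophages (4.48, SE 0.32, adjusted p = 0.552), and Rims2, a gene of vesicle release, at 5.03 and 8.60 (adjusted p = 0.586). Bgn, the proteoglycan biglycan, was at 6.02 and 8.71, Timp1, an inhibitor of metalloproteinases, at 6.72 and 8.90, and Laptm4b, a lysosomal membrane protein, at 9.48 and 10.98 (adjusted p = 0.586 for each). In the other direction, Enpp4 was at 9.26 and 6.70 (−2.56, SE 0.13, adjusted p = 0.276) and Cadm1, an adhesion molecule, at 12.87 and 11.26 (−1.62, SE 0.10, adjusted p = 0.399). Atp10d, called lower in neutrophils, was at 9.90 and 6.99 in macrophages and Rbm45, an RNA-binding protein, differed by −3.04 (adjusted p = 0.696 for both), and Trpv4, a cation channel, differed by −1.09 (adjusted p = 0.790). With groups that did not overlap, 102 genes were at least 2-fold higher and 99 at least 2-fold lower, and against wild-type replicate 1 alone both knockout arrays were at least 2-fold higher for 30 genes and lower for 29.

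**Figure D3:**
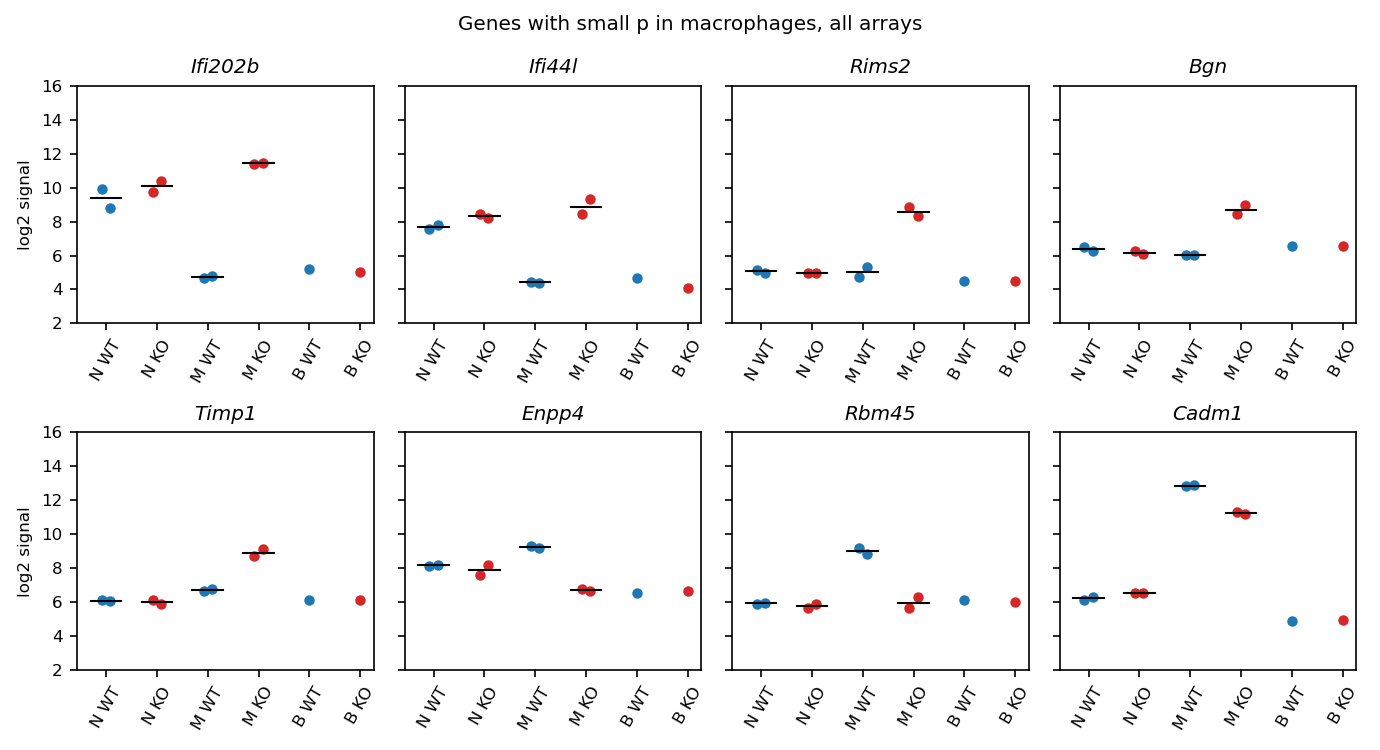
Log2 signal of 8 of the 11 genes named for macrophages, 1 point per array, in neutrophils (N), macrophages (M) and B cells (B), with wild type in blue, knockout in red and a black line at the mean of 2 arrays. Ifi202b lies at 11.42 and 11.46 in knockout macrophages and at 4.67 and 4.79 in wild-type macrophages.

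By list, cell-cycle genes had a median of 1.23 in knockout macrophages (18 of 18 positive, adjusted p = 0.0188, but adjusted p = 0.745 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, lay at 11.75 and 6.65 in wild-type replicates 1 and 2 and at 11.39 and 11.09 in the knockout arrays. Bub1, a spindle checkpoint kinase, lay at 10.90 and 5.83 and at 10.22 and 10.34. Wild-type replicate 2 lay below wild-type replicate 1 in 18 of 18 of these genes, by a median log2 difference of −3.48 (Mki67, a proliferation marker, 8.53 against 12.47). Without that array the list median was −0.51 (17 of 18 negative, adjusted p = 9.79e-12, but adjusted p = 0.811 with an estimated correlation), so the direction was the opposite. Glycolysis genes had a median of 0.37 (11 of 11 positive, adjusted p = 0.0443, but adjusted p = 0.745 with an estimated correlation), with replicate 2 below replicate 1 by −1.07, and a median of −0.08 without replicate 2 (adjusted p = 0.138). That call also ended with no filter (adjusted p = 0.0583), quantile normalization (0.0614), the mean of all probe sets (0.0564) and without probe sets ending in _x_at (0.0529). Cholesterol synthesis genes had a median of −0.24 (adjusted p = 0.616), with a replicate difference of −2.38 (Sqle, squalene epoxidase, 8.17 against 11.48), and a median of −1.37 without replicate 2 (11 of 11 negative, adjusted p = 7.42e-10, but adjusted p = 0.811 with an estimated correlation).

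Genes of mRNA deadenylation and decay had a median of −0.18 (16 of 17 negative, adjusted p = 0.00321, but adjusted p = 0.745 with an estimated correlation). Pan3, a deadenylase subunit, averaged 10.15 in wild type and 9.24 in knockout, while Cnot6l lay at 11.71 and 12.41 in wild-type replicates 1 and 2 and at 11.54 and 11.58 in the knockout arrays. For these the replicate difference was 0.09, and without replicate 2 the median was −0.15 with an adjusted p of 0.0614. No list of the macrophage comparison held with an estimated correlation, where the smallest adjusted p was 0.745, and no list had a member past the threshold over all genes. MHC class II presentation genes had a median of −0.80 (6 of 8 negative, adjusted p = 0.111), with H2-Aa at 5.90 in wild-type replicate 1, 10.49 in wild-type replicate 2 and 5.94 and 5.56 in the knockout arrays. Without replicate 2 the median of that list was −0.13 (adjusted p = 0.90). Macrophage markers had a median of −0.36 (11 of 14 negative, adjusted p = 0.111, replicate difference 0.48, and adjusted p = 0.712 without replicate 2).

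Inflammatory mediators had a median of 0.32 with 4 members positive and 4 negative (adjusted p = 0.616). Ccl2, a monocyte chemokine, lay at 12.70 and 7.98 in the wild-type replicates and 12.91 and 12.73 in the knockout arrays. Over this list replicate 2 lay below replicate 1 by −1.21. Interferon-response genes had a median of −0.19 (adjusted p = 0.571), with Rsad2, an antiviral enzyme, higher (10.20 to 11.49) when adjusted over the list alone. Early response genes had a median of 0.12 (adjusted p = 0.326), and of 0.31 without replicate 2 (11 of 13 positive, adjusted p = 0.00418, but adjusted p = 0.811 with an estimated correlation). Plasmablast markers (median −0.51, adjusted p = 0.145), T cell (0.616), mature neutrophil (0.616), and secondary and tertiary granule (0.546) markers gave no call. For B cell markers, also without a call (adjusted p = 0.717), the median was 0.03 and the mean −0.46. Without replicate 2 the medians were 0.13 for inflammatory mediators, −0.0034 for interferon response, 0.02 for plasmablast, 0.20 for T cell, 0.01 for mature neutrophil, 0.23 for secondary and tertiary granule and 0.15 for B cell markers, none of these called. Lysosome (0.616), class switching (0.571), microRNA machinery (0.616) and Y-linked genes with Xist (0.111) were not called.

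For B cells (1 array per genotype, no test) the differences were small, with an SD of 0.117 across genes and a median of −0.0048. Mmp13, a collagenase, was higher in the knockout (5.98 and 7.33), as were Nqo1, a quinone reductase (6.77 and 7.78), and Cxcl2 (7.44 and 8.44), the 3 genes with a 2-fold difference, chosen after their values were seen, and 0 genes were lower by 2-fold. Among the brighter genes, Slpi, a protease inhibitor (8.55 and 9.16), Rrm2 (10.17 and 10.77), Il5ra, an interleukin 5 receptor chain (8.01 and 8.61), and Ccl22, a chemokine (12.43 and 12.92), had higher knockout values, as did Birc5 (0.49), Egr1 (0.48), Il1rn (0.47), Mid1 (0.45), Glipr1 (0.45) and Ccna2 (0.43). Tmem69 (9.62 and 9.07), Cnr2, a cannabinoid receptor (−0.50), Tbx21, the transcription factor T-bet (11.49 and 11.05), and Gfi1, a repressor (9.85 and 9.42), had lower knockout values, as did Tasor (−0.48), Churc1 (−0.47), Clec2d (−0.45), Iigp1 (−0.42), H1f2 (−0.41) and Fam171b (−0.40). In both B cell arrays, labelled male, Xist, the RNA of the inactive X chromosome, was at 14.19 and 14.18 and the Y-linked Eif2s3y at 3.58 and 3.61, whereas the neutrophil and macrophage arrays had Xist between 5.80 and 6.40 and Eif2s3y between 9.31 and 9.98. This did not differ between the B cell genotypes.

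By list, cell-cycle genes were higher in the knockout B cell array for 17 of 19 members (median 0.20) and cholesterol synthesis genes for 11 of 11 (median 0.21), each above all of the matched random lists (percentile 100). Mature neutrophil genes were higher for 5 of 5 members (median 0.33, percentile 100), among them S100a8 (7.52 and 7.86) and S100a9 (7.27 and 7.70), macrophage markers for 7 of 7 (median 0.12, percentile 97.7), with Cd14 at 6.38 and 6.77, and inflammatory mediators for 9 of 12 (median 0.10, percentile 99.6). Genes of mRNA decay had a median of −0.06 (15 of 17 negative, percentile 2.27). Within the central range were early response (3.93), class switching (5.15), glycolysis (11.4), let-7 targets (13.7), miR-155 targets (13.5), miR-223 targets (37.7), T cell (39.4), microRNA machinery (54.3), interferon response (56.6), miR-122 targets (58.8), NK cell (67.7), B cell (76.9), plasmablast (86.0), MHC class II (87.1) and lysosome (88.1) genes, with the percentile of the list median in parentheses. With 1 array per genotype, none of these differences can be set against the spread between replicates.

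**Figure D4:**
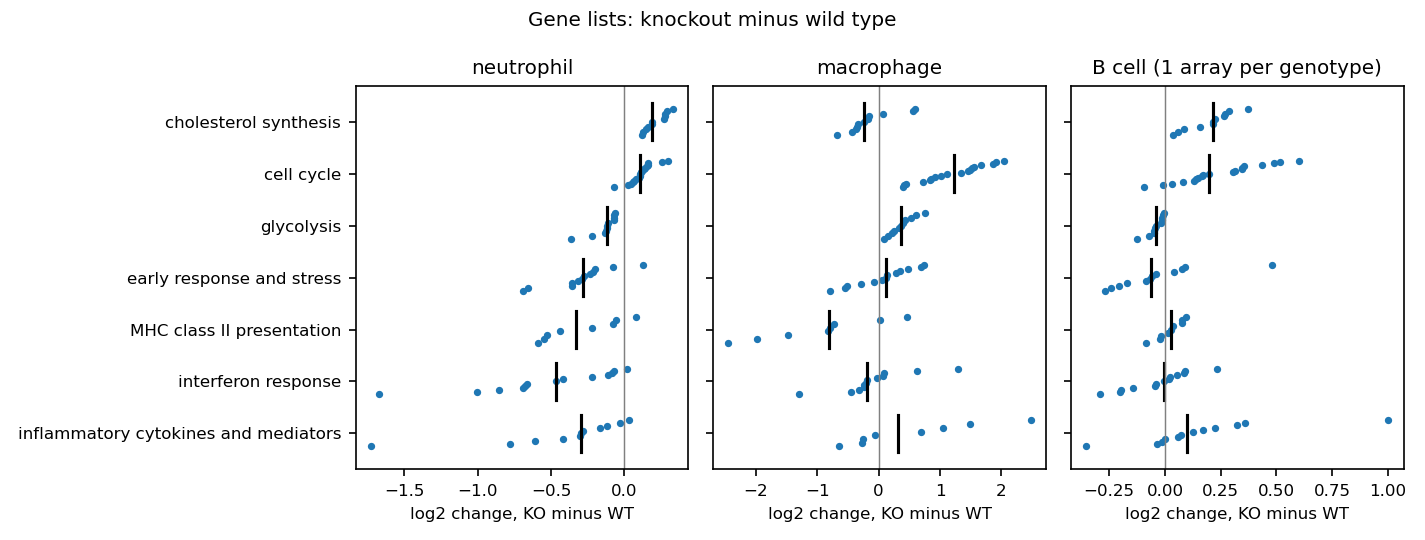
Log2 difference, knockout minus wild type, of the genes of 7 lists in neutrophils, macrophages and B cells, 1 point per gene with a black line at the list median and with x scales that differ between panels. Cholesterol synthesis genes have medians of 0.19 in neutrophils, −0.24 in macrophages and 0.21 in B cells, and the macrophage median is −1.37 without wild-type replicate 2.

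The series title concerns microRNAs, so reported targets of miR-223 and miR-155 were compared in each cell type. In neutrophils the miR-223 targets had a median of −0.020 (5 of 16 positive, adjusted p = 0.496, and adjusted p = 0.827 with an estimated correlation), and 0 members passed by limma, either over all genes or adjusted over the list alone. In macrophages the miR-223 list had a median of −0.10 (6 of 17 positive, adjusted p = 0.274). The miR-155 targets were lower as a list in macrophages (median −0.11, 14 of 19 negative, adjusted p = 0.0314, but adjusted p = 0.745 with an estimated correlation and 0.311 without wild-type replicate 2). No member passed there, and wild-type replicate 2 lay above replicate 1 by 0.28 for this list. Jarid2, a chromatin regulator, lay at 9.26 and 10.26 in wild-type replicates 1 and 2 and at 8.89 and 8.67 in the knockout arrays. In neutrophils the miR-155 list was lower as well (median −0.05, 14 of 19 negative, adjusted p = 0.0227, but adjusted p = 0.651 with an estimated correlation), with Cebpb (−0.21) lower when adjusted over the list alone. That call ended without wild-type replicate 2 (adjusted p = 0.168), without knockout replicate 1 (0.237), without the variance trend (0.0928) and in the joint fit of 8 arrays (0.293). In B cells the medians were −0.04 for miR-155 targets (13 of 17 negative) and −0.02 for miR-223 targets (9 of 16 negative). Mir155hg, the host transcript of miR-155, lay below the 25th percentile of each neutrophil and macrophage array. It was thus not shown to be above background there, and the lower miR-155 lists in these cells are not read as an effect of miR-155.

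Of the comparison lists, let-7 targets had a median of 0.28 in macrophages (9 of 9 positive, adjusted p = 0.0314, but adjusted p = 0.745 with an estimated correlation, 0.137 with no filter and 0.0592 without wild-type replicate 2). Ccnd1, a cyclin, lay at 13.56 and 11.45 in the wild-type replicates and 13.90 and 13.57 in the knockout arrays, with replicate 2 below replicate 1 by −0.38 over the list. In neutrophils the let-7 list was not called (adjusted p = 0.480), although Hmga2 (−0.57), Arid3b and Ccnd1 fell and Cdc25a and Myc rose when adjusted over the list alone. The miR-122 targets were not called in neutrophils (adjusted p = 0.488, with Klf6 lower when adjusted over the list alone) or in macrophages (adjusted p = 0.111).

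The comparison of wild-type neutrophils with wild-type macrophages (n = 2 per group) described the identity of the cells, with signals scaled between the cell types. Stfa2l1, a stefin of granulocytes, rose from 3.14 in macrophages to 14.85 in neutrophils (log2 fold change 11.71, SE 0.13, adjusted p = 0.000464), S100a9, a calcium-binding protein abundant in neutrophils, from 4.89 to 15.53, and Mpo, the granule enzyme myeloperoxidase, from 4.92 to 14.80. Pmp22, a membrane protein, fell from 13.88 to 5.53 (−8.35, SE 0.14, adjusted p = 0.000464) and Cd36, a scavenger receptor, from 13.98 to 6.44. In total 1965 genes were higher and 2335 lower in neutrophils, and groups did not overlap in 77.8% of genes (33.3% by chance). The other genes named on the neutrophil side, Stfa3, Lcn2, Chil3, Ngp, Wfdc21, Lrg1 and Plac8, were higher by 9.68 (Plac8) to 11.14 (Stfa3), and those on the macrophage side, Cd5l, Gas6, B3galnt1, Igf1, Atp6v0d2, Akap2, Gask1b and Blnk, had changes from −7.13 (Cd5l) to −6.36 (Blnk). The macrophage signals of the 10 genes higher in neutrophils lay between 3.14 (Stfa2l1) and 5.25 (Ngp), below the filter's limit of 6.48, and the neutrophil signals of the 10 lower between 3.76 (Akap2) and 6.81 (Igf1), so these sizes were read against signals at or near background.

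All 6 primary granule genes (median 8.75, adjusted p = 1.49e-05) and all 10 secondary and tertiary granule genes (8.48, adjusted p = 1.99e-08) rose in neutrophils. Mature neutrophil genes were higher (median 6.90, adjusted p = 1.49e-05), 8 members rising and Clec4d falling with a change of −0.87. Eosinophil, basophil and mast cell markers rose for 5 of 5 (5.69, adjusted p = 5.67e-05). Of 14 macrophage markers 12 fell (median −2.87, adjusted p = 9.87e-07), while Csf1r (−0.80) and Fcgr1 (−1.06) did not pass. Lysosome genes were lower in neutrophils (−0.88, adjusted p = 0.000695), 10 members falling and Lamp2 rising by 0.55. Glycolysis genes were higher (1.13, 11 of 11 positive, 4 past the threshold, adjusted p = 0.00289), and so were early response genes (1.95, 6 members rising and 1 falling, adjusted p = 0.0243). With an estimated correlation the adjusted p of these 8 lists was 0.563 to 0.713. That version called none of them despite their size, so it could hardly decide the smaller knockout differences either. Fry did call these lists, with adjusted p from 0.000375 (secondary and tertiary granule) to 0.0411 (early response), apart from glycolysis (0.118). Between genotypes fry called no list, with a smallest adjusted p of 0.167 in neutrophils and 0.670 in macrophages. Wild-type macrophage replicate 2 lay below replicate 1 by −1.07 for glycolysis genes and above it by 0.38 for early response genes and by 0.48 for macrophage markers.

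The adjusted p of the remaining lists was 0.0740 for interferon response, 0.0959 for cell cycle, 0.114 for cholesterol synthesis, 0.15 for miR-155 targets, 0.153 for microRNA machinery, 0.173 for miR-223 targets, 0.235 for mRNA decay, 0.236 for class switching, 0.251 for inflammatory mediators, 0.277 for B cell markers, 0.293 for Y-linked genes with Xist, 0.441 for miR-122 targets and MHC class II, 0.466 for let-7 targets, 0.493 for T cell markers and 0.505 for plasmablast markers. For T cell markers the median was 0.62 and the mean −0.10, and for plasmablast markers −0.07 and 0.24. Cell type and any batch cannot be told apart here, since the labels give no batch. For the markers a batch alone is argued against. All 10 secondary and tertiary granule genes passed higher in neutrophils and 12 of 14 macrophage markers passed lower, as the labels have it. Leaving out a macrophage array raised the counts (4081 higher and 4324 lower without replicate 1, 4253 and 4358 without replicate 2), leaving out a neutrophil array lowered them (319 and 244, 327 and 249), and no filter gave 3694 higher and the 60th percentile filter 1247 higher.

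Whether the knockout effect differed between neutrophils and macrophages was tested as an interaction (8 arrays). By limma 0 of 10106 genes passed, with 574 at an unadjusted p under 0.05. Cadm1 had the smallest adjusted p (difference 1.89, SE 0.13, adjusted p = 0.0585), Ifi202b had a difference of −6.02 (adjusted p = 0.132) and Hebp1 of 3.48 (adjusted p = 0.159), these 3 chosen after their values were seen. Of the 39 genes called in neutrophils, 31 were measured in macrophages, where 19 differed in the same direction, 12 of them with groups that did not overlap, while 3 (Hebp1, Lrmp and Usp46) differed in the opposite direction with groups that did not overlap. In B cells 27 were measured, of which 9 differed in the same direction. Across genes, which are not independent replicates, Pearson's r between the knockout effects was 0.183 for neutrophils and macrophages (Spearman's rho 0.188, 56.6% of genes with the same sign), 0.0508 for neutrophils and B cells (0.105, 53.9%) and 0.214 for macrophages and B cells (0.198, 56.5%). Without wild-type macrophage replicate 2 the r was 0.0128 with neutrophils (rho −0.0838, 46.3% of genes with the same sign) and −0.00827 with B cells (rho 0.0253, 51.1%). The rho with neutrophils changed sign. Without wild-type macrophage replicate 1, 4076 genes passed the interaction test and without replicate 2, 363, while 6 passed with no filter and 1 with no variance trend.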

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

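The tests of exchanged samples, of macrophages replaced by other cells, of neighbouring genes in neutrophils, of the controls for neighbouring genes, of the granulocyte mix and of the wider set of other cell types were chosen only after the result was seen, as were the list tests of the difference between cell types.

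Wild-type macrophage replicate 2 stood apart from replicate 1 (SD of the log2 difference 0.722, against 0.216 between the knockout arrays), with lower cell-cycle (median −3.48) and cholesterol synthesis (−2.38) genes and higher MHC class II genes (1.94). Different scaling of that array is argued against, since the ratio of the wild-type to the knockout replicate SD was 3.34 after quantile normalization and 3.35 as deposited, and macrophages mostly replaced by cells without macrophage markers are argued against for the lower genes, since the 14 macrophage markers differed by a median of 0.48 (the lowest, Msr1, by −1.28). An exchange with a knockout macrophage sample is argued against too, since the knockout arrays lay nearer to each other than to wild-type replicate 1 (SD ratio 0.751), whereas the test planned for it (34 of 59 genes nearer to replicate 1) decided nothing, and a single wrong label or an exchange with an outside sample stays open. For the genes that were higher, a smaller share of other cells, or cells that carry macrophage markers too, cannot be told apart from a different state of the macrophages: the highest marker list, plasmablast, differed by a median of 0.578 over 8 members, with Ighm at 10.77 and 13.39 in replicates 1 and 2 but Mzb1 at 6.30 and 6.46 and Cd79b at 5.85 and 6.12, and the single array keeps it open. A different growth state of the culture or animal may also account for it, and no biological explanation was tested, since no group of the design separates the wild-type samples.

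In macrophages 13 genes had a gap over 1.5 on the log2 scale between genotypes, 9 higher (Ifi202b, Ifi44l, Rims2, Uchl1, AA467197, Bgn, Zfp874a, Cyp1b1 and Timp1) and 4 lower (Cadm1, Enpp4, Atp10d and Rbm45), a set chosen after its values were seen. The other 2 of the 3 splits of the 4 arrays gave 0 such genes. Each of those splits sets the 2 knockout arrays against each other, and these differed by over 1 in 50 of 10916 genes. A gap over 1.5 was thus nearly excluded in advance, and 3 splits are too few for a share under 0.05. Spread between arrays as the cause of these 13 genes stays open. Chromosome segments of another strain around the deleted gene, a candidate explanation, would put changed genes next to each other, and of the 50 macrophage genes with the smallest p and groups that did not overlap, 10 had another within 5 tested genes (0.25% of random draws had as many), but the 50 largest differences between the wild-type arrays had 8 (1.9% of draws), while sets chosen alike from the other splits had 5 and 0, so the controls differ and this cannot be told apart from co-regulated neighbours. In neutrophils 4 of the 39 called genes had such a neighbour (14.2% of draws), Bend4 with Atp10d and Hebp1 with Emp1. The 39 genes with the smallest p and groups that did not overlap in the other splits gave 8 (0.37% of draws) and 0. Of the 100 with the smallest p and groups that did not overlap 22 had one (0.17% of draws), but 100 chosen alike from the other splits of the arrays gave 19 and 6 (in macrophages 19, against 15 and 6), so co-regulated neighbours stay open here too. Named genes with such a neighbour among the 100 were Sash1, Dhx40, BC018473, Bend4, Atp10d, Hebp1 and Emp1 in neutrophils, and Ifi202b and Laptm4b in macrophages. The other named genes of each comparison had none. Hebp1 and Emp1 lay in a run with Lockd and Fam234b, and Ifi202b lay near Ifi209. An effect of the deleted gene itself stays open and was not tested, since the labels do not name it.

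In knockout neutrophils early response genes and inflammatory mediators were lower by medians of −0.28 and −0.29. Neither list was called by camera at an estimated correlation (adjusted p = 0.371 for each) or by fry (0.167 for each). Scaling between arrays is argued against, as the early response median was −0.277 after quantile normalization. A different mix of immature and mature granulocytes may contribute: the mean of the mature list was lower (−0.098, replicate difference 0.0811) and that of the primary granule list higher (0.0911, replicate difference 0.0440), but these are smaller than the change in question and the idea came from the same lists. Primary granule medians per array (14.38 to 14.52) lay near the array maxima (15.33 to 15.35), so these sizes may not compare. Cells of another type cannot be told apart: the median furthest from 0 among the lists tested first was −0.013 (B cell, 4 members), yet T cell markers went both ways with Thy1 higher by 1.26, and the eosinophil, basophil and mast cell list left out of that test had a median of 0.29, so the bound set for it was too narrow. A genotype effect on these genes stays open beside a difference in handling, which was not tested.

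The knockout effect differed between neutrophils and macrophages in 7 lists by camera at the preset correlation, with adjusted p of 0.590 to 0.667 at an estimated correlation, and each value is the median of the neutrophil minus the macrophage effect. Without wild-type macrophage replicate 2 none of the calls held with an estimated correlation either, with adjusted p of 0.328 for cell-cycle and early response genes and 0.752 for interferon-response genes. Cholesterol synthesis genes, not called with 8 arrays (0.42, adjusted p = 0.255), differed most without that array (1.61, adjusted p = 2.31e-15, but adjusted p = 0.328 with an estimated correlation). For let-7 targets the difference was −0.37 (adjusted p = 0.0109), and −0.28 without wild-type macrophage replicate 2 (adjusted p = 0.0682). For miR-122 targets it was −0.26 (adjusted p = 0.0479), and −0.16 without that array (0.35). For interferon-response genes it was −0.60 (adjusted p = 0.0479), and −0.86 without that array (0.00189). For cell-cycle genes it was −1.10 (adjusted p = 0.0479), and 0.60 in the opposite direction without that array (4.56e-16). For glycolysis genes it was −0.48 (adjusted p = 0.0109), and −0.05 without that array (0.488). For early response genes it was −0.30 (adjusted p = 0.0412), and −0.52 without that array (5.96e-06). For mRNA deadenylation and decay genes it was 0.13 (adjusted p = 0.0109), and 0.11 without that array (0.378).

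In 5 named genes outside the filtered interaction fit every knockout array lay on one side of the wild type in neutrophils and on the opposite side in macrophages. The difference was not tested there, since each of the 5 was below its limit in 1 of the cell types. For Slc15a2 its size rests largely on wild-type macrophage replicate 2 (8.50, against 5.62 in replicate 1). The opposite direction otherwise rests on signals near background, and it is not shown as a response. Differences given for the 5 are of signals as deposited, and their adjusted p are from the scaled fit. Of the named genes inside that fit, Hebp1 (macrophages 10.15 and 10.25 in wild type, 9.95 and 9.76 in knockout) and Cadm1 (neutrophils 6.15 and 6.31, 6.52 and 6.53) also lay on opposite sides, and the test of the difference did not pass for either (adjusted p = 0.159 and 0.0585). Ptgs2 had a difference of −3.27 (adjusted p = 0.0378 in the fit without a filter), with macrophage signals of 3.85 and 3.57 in wild type and 5.38 and 5.12 in knockout. Rims2 had a difference of −3.66 (0.0466 without a filter), and its neutrophil signals all lay between 4.95 and 5.13. Bgn had a difference of −2.92 (0.0545 without a filter), with neutrophil signals of 6.53 and 6.26 in wild type and 6.24 and 6.08 in knockout. Tesc had a difference of −1.41 (0.0765 without a filter), with macrophage signals of 6.18 and 6.06 in wild type and 6.35 and 6.26 in knockout. Slc15a2 had a difference of 2.95 (0.884 without a filter), with wild-type macrophage signals of 5.62 and 8.50.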

How the results depend on the processing

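No named gene reversed its direction under the alternatives tried. Neither microRNA target list did so by camera, whose direction is that of the list against the other genes. The mean deviation of miR-223 targets was 0.0066 and 0.0148 in the wild-type neutrophil arrays and −0.048 and 0.027 in the knockout ones. The 2 knockout arrays thus lay on opposite sides of the wild type for that list. Array weights were chosen after the data were seen. The 19 higher and 20 lower genes of neutrophils became 11 and 13 with the 60th percentile filter (24 shared), 0 and 1 without the variance trend (599 and 585 at an unadjusted p under 0.05 by limma), 0 and 0 with the replicate block (639 and 660 unadjusted) and 0 and 0 in the joint fit of 8 arrays (116 and 139 unadjusted). The replicate block leaves fewer degrees of freedom and the joint fit takes its spread also from macrophages, whereas the cause for the variance trend was not tested. Leaving out each replicate gave 12 to 29 higher and 13 to 36 lower. Quantile normalization gave 23 and 23, and array weights 16 and 21. For macrophages, the 1 higher and 0 lower became 0 higher with the 60th percentile filter (131 unadjusted) and with the replicate block (218 unadjusted), 14 and 7 in the joint fit, 3 and 1 with every probe set tested, and 0 to 2449 higher and 0 to 1943 lower when each replicate was left out, the highest without wild-type replicate 1. Ifi202b lies under the 60th percentile, which ended its call there, and the causes of the others were not tested. Adjusted p for miR-155 targets in macrophages was 0.745 with an estimated correlation, 0.670 by fry, 0.0145 with the replicate block and 0.0163 to 0.311 on leaving out each replicate. The miR-223 targets in neutrophils stayed above the threshold throughout (0.189 to 0.956 on leaving out each replicate). For wild-type neutrophils against macrophages, higher genes numbered 3694 with no filter and 1247 with the 60th percentile filter, where the number of genes tested changes, and leaving out each replicate gave 319 to 4253 higher and 244 to 4358 lower. The interaction gave 6 genes with no filter, 1 (Cadm1) with no variance trend, and 0 to 4076 on leaving out each replicate, the causes not being tested. Where an arm held 1 array, that array was assumed to vary like the other group. Among named genes, 159 comparisons of a gene with an alternative kept their side of the threshold and 95 lost the call in neutrophils, 111 kept it, 19 gained and 3 lost a call in macrophages, and 217 kept it between cell types. In B cells 40 of 40 values moved by less than the SD, and the miR-155 median was −0.03 after quantile normalization. The correlation of arrays with the same replicate number was 0.131 in neutrophils and 0.0135 in macrophages over 2 pairs each, so the numbers are not shown to pair samples. Offset alternatives were not run, since the deposited table is already on the log2 scale. Signal over background limits dim genes such as Ifi202b, Ifi44l and Rims2 in wild-type macrophages, which lay at 4.40 to 5.32, below the filter's limit of 6.52.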

Other observations

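No tests were added for this part, and the genes were chosen after their values were seen, apart from list members. In neutrophil arrays, genes of cell division had high signals beside granule genes. Mki67, a proliferation marker, lay between 11.88 and 12.38 and Top2a, a topoisomerase of dividing cells, between 12.30 and 12.47, while Mpo lay between 14.60 and 14.79 and Elane between 14.58 and 14.74. Csf1r, the receptor for macrophage colony-stimulating factor, was bright in neutrophil arrays as well (13.32 to 13.54) beside 14.15 to 14.99 in macrophages. Over the cell-cycle list the median level was 11.21 to 11.37 in neutrophils, 10.91 to 11.42 in macrophages other than wild-type replicate 2, 7.43 in that array, and 9.18 and 9.52 in B cells.

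In B cell arrays a cytokine and a microRNA host transcript had high signals. Il6, the cytokine, was at 14.07 in both, against 5.56 to 5.92 in neutrophils and 3.58 to 3.82 in macrophages. Mir155hg, the host transcript of miR-155, was at 10.78 in the wild-type and 10.73 in the knockout B cell array, 3.91 to 3.99 in neutrophils and 4.11 to 4.62 in macrophages. The last 2 ranges lay below the 25th percentiles of those arrays (4.68 to 4.76 in neutrophils and 4.89 to 4.98 in macrophages). Jchain, the joining chain of secreted antibodies, was at 8.04 and 7.20, while Cd79b, a chain of the B cell receptor, was at 13.64 and 13.59.

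Xist was at 14.19 and 14.18 in the B cell arrays, while Kdm5d (3.42 and 3.34) and Uty (4.28 and 4.01) lay low there and at 7.91 to 9.09 and 7.51 to 9.23 in the other arrays, although all samples were labelled male. Lists with too few tested genes were NK cell (0), erythroid (2) and dendritic cell (1) in the neutrophil, macrophage and wild-type comparisons, also primary granule (1) and eosinophil, basophil and mast cell (0) in macrophages, and in B cells primary granule, secondary and tertiary granule, erythroid and dendritic cell (2 each), eosinophil, basophil and mast cell (1) and Y-linked genes with Xist (1).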
